A study of Macaca mulatta with 12 samples.

How the data were processed

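RNA from 12 corpora lutea of rhesus macaques was measured on one-colour Affymetrix rhesus arrays with biotin-labelled targets, 1 array per corpus luteum. Per the labels, the 12 arrays are biological replicates, 4 in each of 3 groups: mid-late (days 10 to 12 after the LH surge, the baseline group), late functional (days 14 to 16, serum progesterone above 1.5 ng/ml) and late regressed (days 14 to 16, serum progesterone below 0.5 ng/ml). Groups and replicate numbers were taken from the sample titles.

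The deposited table holds log2 values, 1 per probe set and array. The authors' processing used RMA, per the submitters' processing notes, and its version and settings are not given in the sources used here. The log2 scale was read from the range of the values. RMA commonly includes a quantile step that forces arrays towards one distribution, so a change in total RNA per cell cannot be seen in such values. Medians of the 12 arrays nevertheless ran from 4.31 to 4.43. Neither scan dates nor batches are given in the sources used here, so no batch could be tested.

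The table holds 52865 probe sets. 158 array controls (99 AFFX and 59 RPTR) were left out, which left 52707 tested probe sets. The platform annotation gave exactly 1 gene symbol for 24956 probe sets, several for 361 and none for 27390 of those tested. Of the symbols, 24616 were looked up by Entrez ID in a current RefSeq gene table (assembly T2T-MMU8v2.0), and 0 changed. No coordinates were used. A gene with several probe sets was represented by the probe set with the highest mean over the 12 arrays. That gave 14132 genes, 12993 of them with a symbol that is not a LOC identifier. A further set of 674 tested probe sets carries the identifier prefix NC and has no gene symbol. What these probe sets target is not given in the sources used here, and they served only as a set of mostly low-signal probe sets.

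Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with all 12 arrays in one fit of group means and no covariate. Adjusted p-values are Benjamini-Hochberg values within a comparison, and a probe set was called at an adjusted p below 0.05. limma's moderated F test was used for any difference among the 3 groups. Shifts of 33 gene lists, 22 of pathways and 11 of cell types, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated from the data. Single measures per array were compared with exact two-sided permutation tests, whose smallest p with 4 against 4 arrays is 0.0286. The number of arrays limits the precision of all values.

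Named genes followed a rule: a panel of 12 luteal genes whatever their values; the 5 largest increases and the 5 largest decreases with an adjusted p below 0.05, at least a 2-fold difference and no overlap between the arrays of the groups; and, for each list with a called shift or at least 1 in 5 of its members called, up to 4 called members, or up to 2 members as values where none was called. Panel genes with no probe set under their symbol in the annotation used, such as LHCGR, CYP11A1, SCARB1, ABCG1 and PTGFR, are not analysed here. Groups, tests, lists, this rule and most alternatives were fixed before the data were examined.

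RNA quality was measured as the log2 difference between the 3′ and 5′ control probe sets of beta-actin and GAPDH. Alternatives comprised a filter on low signal, median centring, renewed quantile normalization, a trended robust prior, fits of only the groups compared, the replicate number as a block, array weights, the 3′ to 5′ difference as a covariate, removal of cross-hybridising probe set types, a 2-fold minimum, the mean over a gene's probe sets and leaving out each array. A pseudocount alternative for linear values was not run, because the values are log2. After the data were seen, 3 more were added: late regressed arrays 2 and 3 left out together, only probe sets above the 95th percentile of the NC set (4.64), and the per-array mean of the NC set as a covariate.

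The scripts were tested on simulated data with the real means and residual spreads of the 52707 probe sets and 200 changed ones. For late regressed against mid-late, 39.1% of changes of 0.5 log2, 86.7% of changes of 1 and 98.4% of changes of 2 were recovered. For late regressed against late functional the shares were 35.5%, 78.6% and 98.5%, and for late functional against mid-late 44.1%, 77.9% and 93.8%. Unchanged probe sets were called 6, 9 and 8 times in these comparisons. The simulated noise was drawn independently for each value, with 1 spread per probe set for all groups. The real late regressed arrays differed more among themselves than those of the other groups. These shares therefore test the scripts and do not give the power in the real data.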

Results

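The corpus luteum is the transient gland that forms from the ovulated follicle and secretes progesterone. In the series, corpora lutea were collected from rhesus macaques in the second part of the luteal phase. Messenger RNA was profiled in 4 mid-late corpora lutea (days 10 to 12 after the LH surge) and in late ones at days 14 to 16. Of the late ones, 4 went with serum progesterone above 1.5 ng/ml (late functional) and 4 with serum progesterone below 0.5 ng/ml (late regressed). Values are RMA log2 array values as deposited, given as mean ± SD with n = 4 arrays per group, and differences are log2 differences of group means with the SE of limma's fit. Adjusted p-values are from limma.

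The late regressed arrays differed most among themselves. On the first principal component, with 40.8% of the variance, late regressed arrays 2 and 3 scored 93.2 and 81.6, and the other 10 arrays lay between -43 and 12.6. Array 2 also had the largest difference between 3′ and 5′ control signal, with a mean of 2.52 over beta-actin and GAPDH, and array 3 had 0.46, below the mid-late mean of 0.66 ± 0.03. This difference did not separate late regressed from mid-late arrays (exact permutation p = 0.886) or from late functional ones (exact permutation p = 0.714). It was 0.08 lower in late functional than in mid-late arrays by its group means, 0.59 ± 0.04 and 0.66 ± 0.03, with an exact permutation p of 0.0286 that became 0.0858 when adjusted over the 3 comparisons. The mean of the 674 probe sets with the prefix NC was 3.69 ± 0.05 in mid-late, 3.57 ± 0.04 in late functional and 3.55 ± 0.05 in late regressed arrays. Both late groups lay below mid-late (exact permutation p = 0.0286 for each, 0.0429 adjusted over the 3 comparisons).

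**Figure D1:**
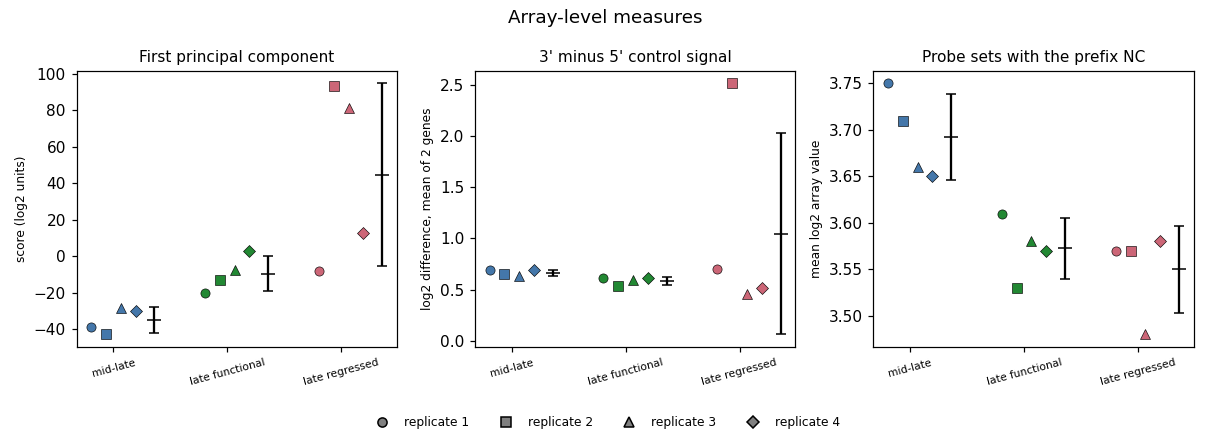
Array-level measures in the 3 groups: score on the first principal component, 3′ minus 5′ control signal (log2) and mean log2 value of the probe sets with the prefix NC; symbols are the 4 arrays of a group and black bars the mean ± SD. Late regressed arrays 2 and 3 score 93.2 and 81.6 on the component, and only array 2 has a 3′ minus 5′ difference above 0.7.

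Late regressed against mid-late corpora lutea compares glands at low serum progesterone with the baseline stage. HSD3B2, which encodes the enzyme that converts pregnenolone to progesterone, fell from 11.66 ± 0.38 to 8.55 ± 0.47, an 8.63-fold difference (log2 difference -3.11, SE 0.33, adjusted p = 0.00548). CYP19A1, the aromatase that makes oestrogens, fell from 11.64 ± 0.56 to 8.56 ± 1.52 (adjusted p = 0.0137; log2 difference -3.09, and -1.82 without late regressed arrays 2 and 3), and HSD11B1, which interconverts cortisone and cortisol, fell from 11.35 ± 0.31 to 8.22 ± 0.69 (adjusted p = 0.00555). STAR, which carries cholesterol into mitochondria, averaged 11.32 ± 1.77 against 13.52 ± 0.12 and missed the threshold (log2 difference -2.20, adjusted p = 0.0508). Its values on late regressed arrays 1 to 4 were 13.54, 10.14, 9.68 and 11.92, and without array 1 it was called (adjusted p = 0.00301). Of 25 alternatives, 4 called STAR, this one among them, and 21 did not. Without arrays 2 and 3 its difference shrank to -0.79 (adjusted p = 0.221). The oxysterol receptor gene NR1H3 averaged 7.86 ± 1.07 against 6.52 ± 0.23 (adjusted p = 0.0576) and was called without late regressed array 1 (0.0105) or array 4 (0.04). Its difference of 1.34 shrank to 0.431 without arrays 2 and 3 (adjusted p = 0.257). The probe sets of ABCA1 (4.01 ± 0.14 against 3.95 ± 0.03) and PGR (3.80 ± 0.29 against 3.64 ± 0.12) lay at low signal in both groups and were not called.

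The largest decreases by the fixed rule were DEFB122 (a beta-defensin gene, 22.5-fold, adjusted p = 0.00643), DHRS9 (11-fold, adjusted p = 0.00933) and ODAM (10.6-fold, adjusted p = 0.00555). MRAP (the melanocortin receptor accessory protein, 9.83-fold, adjusted p = 0.0108) and HSD11B1 (8.75-fold) followed. The largest increases were LPL (lipoprotein lipase, 9.38-fold, adjusted p = 0.0327), ADAMDEC1 (8.6-fold, adjusted p = 0.0392) and the chemokine gene CCL3 (8.32-fold, adjusted p = 0.0434). EVI2A (7.54-fold, adjusted p = 0.0106) and CYBB (a subunit of the phagocyte NADPH oxidase, 5.89-fold, adjusted p = 0.0472) came next. ODAM in late regressed (4.59 ± 0.64) and ADAMDEC1 in mid-late arrays (3.97 ± 0.13) lay below the 95th percentile of the NC set (4.64). The size of both folds and their places in this order are therefore uncertain. ADAMDEC1 values on late regressed arrays 1 to 4 were 4.99, 8.18, 8.82 and 6.29. For LPL the late regressed values were 6.96, 10.65, 10.77 and 6.81 on arrays 1 to 4, and for CCL3 they were 7.01, 11.16, 11.19 and 7.99. Without arrays 2 and 3, the MRAP difference shrank from -3.30 to -2.14 with its call kept. LPL shrank from 3.23 to 1.32 and kept its call (adjusted p = 0.0426). Calls were lost for ADAMDEC1 (3.1 to 1.67, adjusted p = 0.24), CCL3 (3.06 to 1.22, adjusted p = 0.185) and CYBB (2.56 to 0.92, adjusted p = 0.155). EVI2A lost its call with a smaller decline (2.91 to 2.05, adjusted p = 0.0539). Of the 12 fits that each left out 1 array, LPL was called in 6, ADAMDEC1 in 3, CCL3 in 2 and CYBB in 2. EVI2A, HSD3B2, CYP19A1 and the 5 largest decreases were called in all 12.

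**Figure D2:**
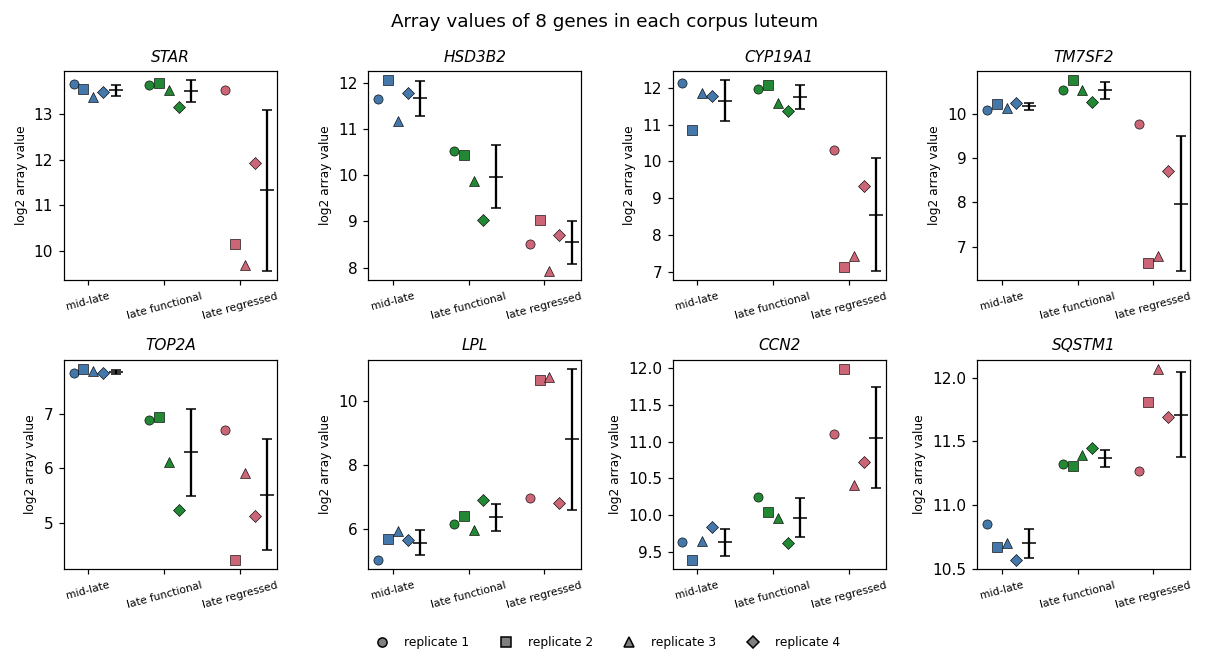
Log2 array values of STAR, HSD3B2, CYP19A1, TM7SF2, TOP2A, LPL, CCN2 and SQSTM1; symbols are the 4 arrays of a group and black bars the mean ± SD. HSD3B2 is lowest in the late regressed group (8.55 ± 0.47), and late regressed arrays 2 and 3 hold the lowest STAR values, 10.14 and 9.68.

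Gene lists for steroid and cholesterol synthesis and for proliferation lay lower in late regressed corpora lutea. Of 15 measured members of the LH receptor and progesterone synthesis list, 3 fell (HSD3B2, FDXR at -1.66 and GATA6 at -0.55), 0 rose and 12 did not pass; adjusted over the list alone, 10 fell and 1 rose. The list was called lower by camera (adjusted p = 0.00566; adjusted p = 0.418 with an estimated correlation). In the cholesterol synthesis list TM7SF2 (-2.19), STARD4 (-1.89) and CYP51A1 (-1.34) fell, 12 of 15 members did not pass, and 11 fell when adjusted over the list alone (camera adjusted p = 0.00125; adjusted p = 0.418 with an estimated correlation). Of 17 cell cycle genes, 8 fell and 9 did not pass, with 11 falling adjusted over the list alone. They included TOP2A (-2.24), CCNB2 (-1.49), CCNB1 (-1.28) and MKI67 (-1.27), and camera gave an adjusted p of 1.66e-05 (adjusted p = 0.418 with an estimated correlation). That estimate was 0.567, against the preset 0.01. Of 21 oxidative phosphorylation genes UQCRFS1 (-0.56) and NDUFA8 (-0.38) fell, and 7 fell adjusted over the list alone (camera adjusted p = 0.00284; adjusted p = 0.436 with an estimated correlation). Beside these decreases, the macrophage list averaged 0.65, 0.65, 1.64 and 0.30 above its mid-late mean on late regressed arrays 1 to 4. The means of the cholesterol synthesis list on these arrays were -0.129, -1.295, -1.375 and -1.118, and its mid-late arrays ran from -0.284 to 0.265. Those of the LH receptor and progesterone synthesis list were -0.33, -1.05, -1.26 and -0.50. Without arrays 2 and 3, of which array 2 has the largest 3′ to 5′ difference, the mean of this last list shrank from -0.78 to -0.42. That of cholesterol synthesis shrank from -0.98 to -0.62 and that of oxidative phosphorylation from -0.31 to -0.19. Of the late regressed arrays left, only array 4 lay below the mid-late range of the cholesterol synthesis list. The cell cycle list did not shrink (-0.78 with and -0.82 without them). All 4 list calls remained, but of the genes named here only HSD3B2 and GATA6 kept theirs (FDXR 0.191, TM7SF2 0.0657, STARD4 0.173, CYP51A1 0.147, TOP2A 0.0712, CCNB2 0.12, CCNB1 0.142, MKI67 0.0539, UQCRFS1 0.238, NDUFA8 0.158). The differences of CCNB2 (-1.49 to -1.44), CCNB1 (-1.28 to -1.23) and MKI67 (-1.27 to -1.33) hardly moved, so their lost calls go with fewer arrays and not with a smaller difference. With the NC mean as a covariate, the LH receptor and progesterone synthesis call was lost. The calls of these 4 lists held whichever single array was left out. Of their members GATA6, TOP2A and MKI67 were called in all 12 such fits, CYP51A1 in 9, CCNB2 in 7, TM7SF2 and STARD4 in 6, CCNB1 in 5, FDXR in 4, NDUFA8 in 3 and UQCRFS1 in 2. MKI67 (3 probe sets) had no other probe set called, TOP2A had 1 more called, and GATA6 has 1 probe set.

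Lists of lysosomal, complement, stress and early response genes lay higher, and so did a mixed list of oxysterol receptor targets and efflux genes. CTSH (1.04), SQSTM1 (1.01), ASAH1 (0.99) and ATG5 (0.58) rose among 17 lysosome and autophagy genes, 13 did not pass, and 5 rose adjusted over the list alone (camera adjusted p = 0.0175; adjusted p = 0.418 with an estimated correlation). Of 17 immediate early genes 6 rose, among them EGR2 (2.55), ATF3 (1.90), CCN1 (1.77) and CCN2 (1.43), and 1 fell; adjusted over the list alone, 7 rose and 2 fell (camera adjusted p = 0.0263; adjusted p = 0.436 with an estimated correlation). In the list of oxysterol receptor targets and cholesterol efflux, CD36 (1.92), MYLIP (0.95), NPC2 (0.74) and SREBF1 (0.59) rose and 1 member fell of 13, with 7 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.041; adjusted p = 0.418 with an estimated correlation). Its member ABCA1 lay at low signal and was not called (limma adjusted p = 0.621), and ABCG1 had no probe set under its symbol. The label efflux below stands for the whole mixed list and not for these genes. C5AR1 (2.12) and SERPING1 (1.05) rose of 11 complement genes, and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.0364; adjusted p = 0.418 with an estimated correlation). DDIT3, a transcription factor of the unfolded protein response, rose by 1.20 and was the single called member of 12 in its list, also when adjusted over the list alone (camera adjusted p = 0.0437; adjusted p = 0.418 with an estimated correlation). The early response, efflux, complement and unfolded protein calls were also lost after median centring and with the median filter on signal, and the lysosome call with that filter. Array weights ended the complement and unfolded protein calls. Renewed quantile normalization, the 3′ to 5′ covariate and the mean over a gene's probe sets each ended the unfolded protein call. The NC mean as a covariate ended all 5 calls and changed the tested direction of the complement list. On late regressed arrays 1 to 4 the efflux list averaged 0.16, 0.64, 0.85 and 0.29 and the complement list 0.41, 0.83, 1.09 and 0.31, beside 0.65, 0.65, 1.64 and 0.30 for macrophage genes. Without late regressed array 3 the calls of the lysosome (0.0591), early response (0.0646), efflux (0.124), complement (0.0991) and unfolded protein (0.102) lists were lost. Without mid-late array 1 the last 3 were lost at 0.0557 each. The complement call was lost without mid-late array 2 (0.0522), and without mid-late array 3 those of early response (0.0634), efflux (0.0561) and unfolded protein genes (0.0753). Leaving out late regressed array 1 ended the early response call (0.125) and array 2 the unfolded protein call (0.0738). SQSTM1, MYLIP, SREBF1, CCN2 and DDIT3 were called in all 12 fits without 1 array. ASAH1 and ATG5 were called in 11, SERPING1, EGR2 and ATF3 in 7, NPC2 in 6, CTSH and CCN1 in 3, and CD36 and C5AR1 in 2. Of the genes called in all 12, SQSTM1 (2 probe sets), SREBF1 (3) and CCN2 (3) had no other probe set called. MYLIP had 2 more called, and DDIT3 has 1 probe set.

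Fibroblast and macrophage markers also lay higher. The fibroblast list had 4 members that rose, FBLN1 (1.74), COL14A1 (1.33), DPT (1.29) and GSN (0.92), and 1 that fell of 14, with 6 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.0263; adjusted p = 0.418 with an estimated correlation). The macrophage list was called higher (mean 0.81, camera adjusted p = 0.0263; adjusted p = 0.457 with an estimated correlation) although 0 of its 16 members were called and 5 were when adjusted over the list alone. Its members TYROBP (1.75, adjusted p = 0.0611) and CD53 (1.70, adjusted p = 0.0623) had the largest differences. In lists without a called shift, the endothelial genes CLDN5 (0.70), SOX17 (0.76) and ERG (0.53) rose, SYNPO2 (0.95) rose and MCAM (-0.88) fell among smooth muscle and pericyte genes. Among 17 redox enzymes GSTA3 (-1.91), MGST1 (-1.54) and GSTA1 (-0.72) fell, 2 rose, SOD2 (1.97) being one of them, and 12 did not pass. OAS1 (1.11), IRF1 (0.98) and GBP2 (0.74) rose and IFI27 (-1.03) fell among interferon-stimulated genes, and HSD17B8 (-0.71) fell. The macrophage call was lost without late regressed array 3 (0.0734), mid-late array 1 (0.0922) or mid-late array 2 (0.0585), and the fibroblast call without mid-late array 1 (0.0557) or 2 (0.0502). With the NC mean as a covariate the macrophage list turned to -0.59 and the fibroblast call was lost. Both were also lost after median centring, with either filter on low signal and with array weights. FBLN1, GSN, CLDN5, ERG, GSTA1, OAS1, GBP2 and HSD17B8 were called in all 12 fits without 1 array. IRF1 was called in 10, GSTA3 in 9, SOD2 in 7, SYNPO2 in 6, DPT and MGST1 in 5, IFI27 in 4, and COL14A1, SOX17 and MCAM in 3. Of the genes called in all 12 fits, OAS1 (5 probe sets), ERG (3), GBP2 (3), GSN (2) and GSTA1 (2) had no other probe set called. FBLN1 had 2 more called, and CLDN5 and HSD17B8 have 1 probe set each. The 22 lists without a called shift had camera adjusted p-values from 0.0786 to 0.985. Without late regressed arrays 2 and 3, which carry the highest 3′ to 5′ difference (array 2) and the highest macrophage mean (array 3), the calls of the macrophage, fibroblast, complement, efflux and unfolded protein lists were lost and 6 of the 11 list calls remained.

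In all, limma called 5282 of 52707 probe sets between late regressed and mid-late corpora lutea, 2854 higher and 2428 lower, of which 684 differed at least 2-fold. Among genes with a symbol, 1022 rose and 723 fell. The split by direction depended on scaling, with 54% of calls higher as deposited, 67.6% after median centring and 45.4% after renewed quantile normalization. Of the lower calls, 1249 lay at or below the 95th percentile of the NC set (4.64), and of the higher calls 317. The count was 1620 with only these groups fitted, 2839 with array weights and 0 with the NC mean as a covariate. Without late regressed arrays 2 and 3 together 975 probe sets were called, without array 3 alone 2199, and without mid-late array 1, 2, 3 or 4 the counts were 2167, 2050, 2784 and 3472.

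Late regressed against late functional corpora lutea compares glands of the same days that differ in serum progesterone. FAM210B was the only probe set called by limma, at 10.20 ± 0.11 in late regressed and 9.25 ± 0.18 in late functional arrays (1.93-fold, adjusted p = 0.0275), with 10.17 ± 0.09 in mid-late. Its call held in 4 of the 12 fits without 1 array and was lost with only these groups fitted and with the 3′ to 5′ covariate. It lies below the 2-fold limit of the rule for named genes and was chosen after its values were seen. An unadjusted p below 0.05 was found for 6244 probe sets, where 2635 would be the mean number by chance. Probe sets on the same arrays are correlated, so the number by chance can lie far from that mean. This excess was not tested. HSD3B2 averaged 8.55 ± 0.47 against 9.97 ± 0.68 (adjusted p = 0.174; 0.0391 without late functional array 4), and STAR 11.32 ± 1.77 against 13.50 ± 0.24 (adjusted p = 0.247; 0.0104 without late regressed array 1). Without late regressed arrays 2 and 3 the STAR difference shrank from -2.18 to -0.77 (adjusted p = 0.699), and that of NR1H3 turned from 0.34 to -0.57. NR1H3 had an adjusted p of 0.831, and ABCA1 (0.03) and PGR (0.26) were at low signal.

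By camera at the preset correlation, lists differed in mean between these late groups, although none of their members was called. Single arrays overlapped. The cholesterol synthesis mean was -0.129 on late regressed array 1 and -0.579 on late functional array 4. For LH receptor and progesterone synthesis these means were -0.328 and -0.381. Lower in late regressed arrays were cholesterol synthesis (mean -0.91, camera adjusted p = 1.26e-05; adjusted p = 0.421 with an estimated correlation), with TM7SF2 at -2.55 and DHCR7 at -2.11, and LH receptor and progesterone synthesis (mean -0.58, camera adjusted p = 0.000876; adjusted p = 0.421 with an estimated correlation). Adjusted over the list alone, 9 and 4 of their 15 members were lower. Interferon-stimulated genes (mean -0.63, camera adjusted p = 0.000876; adjusted p = 0.467 with an estimated correlation) included GBP1 at -1.54 and ISG15 at -1.53, and antigen presentation genes (mean -0.45, camera adjusted p = 0.00349; adjusted p = 0.421 with an estimated correlation) included TAP1 at -1.45 and PSMB8 at -1.28. Adjusted over the list alone, 6 interferon genes were lower and 2 higher, and 2 antigen presentation genes were lower. Oxidative phosphorylation (UQCRC2 at -0.77, SDHC at -0.67; camera adjusted p = 0.00414; adjusted p = 0.552 with an estimated correlation), redox enzymes (GSTA3 and MGST1, both at -1.58; camera adjusted p = 0.0175; adjusted p = 0.421 with an estimated correlation) and cell cycle genes (TOP2A at -0.77, TYMS at -0.56; camera adjusted p = 0.0436; adjusted p = 0.745 with an estimated correlation) were also lower. Adjusted over the list alone, 0, 3 and 0 of their members were lower. The cell cycle call was lost after median centring and with either filter on low signal, and the cell cycle and redox calls with the 3′ to 5′ covariate. The cell cycle call held in 5 of the 12 fits without 1 array (0.396 without late regressed array 4). The redox call was lost without late regressed array 2 (0.0707) and the oxidative phosphorylation call without late functional array 2 (0.0536).

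Higher in late regressed than in late functional arrays were the unfolded protein response (DDIT3 at 1.35, TRIB3 at 0.66; camera adjusted p = 0.00349; adjusted p = 0.421 with an estimated correlation), immediate early genes (EGR2 at 2.44, FOS at 1.80; camera adjusted p = 0.0145; adjusted p = 0.494 with an estimated correlation) and fibroblast genes (FBLN1 at 1.23, COL14A1 at 0.95; camera adjusted p = 0.0178; adjusted p = 0.421 with an estimated correlation). Adjusted over the list alone, these had 1, 3 and 2 higher members, and the immediate early list 2 lower ones. The immediate early call was lost without late regressed array 1 (0.112) or 3 (0.0676) or late functional array 3 (0.0553), and the fibroblast call without late regressed array 2 (0.0836) or late functional array 4 (0.0596) and with the 3′ to 5′ covariate. The macrophage list was not called between the groups (mean -0.24, camera adjusted p = 0.584), and the 23 lists without a called shift, this one among them, had camera adjusted p-values from 0.0819 to 0.888. Without late regressed arrays 2 and 3, 0 probe sets were called and 3 of the 10 list calls remained, those of cholesterol synthesis, interferon-stimulated and antigen presentation genes. Of the late regressed arrays left, array 1 had a cholesterol synthesis mean of -0.129, inside the late functional range of -0.579 to 0.402. Array 4 had -1.118. Leaving out late regressed array 1 gave 924 called probe sets, array 4 gave 87, late functional array 4 gave 149, mid-late array 3 gave 2, and each of the other arrays gave 0.

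**Figure D3:**
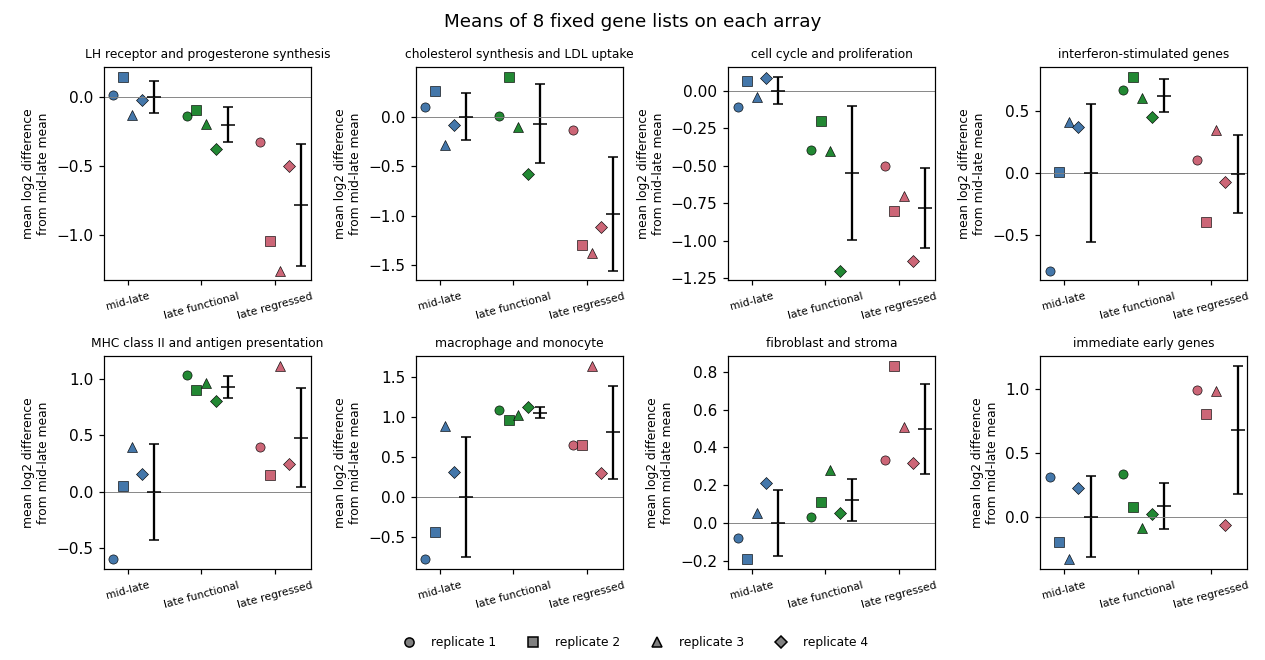
Means of 8 fixed gene lists on each array, as log2 difference from the mid-late mean of each gene; symbols are the 4 arrays of a group and black bars the mean ± SD. The macrophage list is highest on late regressed array 3 (1.64), and the interferon list lies between 0.45 and 0.77 on the late functional arrays.

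Late functional against mid-late corpora lutea compares the late glands with serum progesterone above 1.5 ng/ml with the baseline stage. HSD3B2 fell from 11.66 ± 0.38 to 9.97 ± 0.68 (log2 difference -1.69, SE 0.33, adjusted p = 0.0435), while STAR was 13.50 ± 0.24 against 13.52 ± 0.12 (adjusted p = 0.993). NR1H3 differed by 1.00 (adjusted p = 0.216), and ABCA1 (0.04) and PGR (-0.11) were at low signal. The largest increases were PLAAT4 (6-fold, adjusted p = 0.0363), ST8SIA1 (a ganglioside sialyltransferase, 3.13-fold, adjusted p = 0.0211) and ERAP2 (an aminopeptidase that trims peptides for antigen presentation, 2.98-fold, adjusted p = 0.0195). SAMD9L (2.86-fold, adjusted p = 0.0139) and the receptor gene TLR1 (2.61-fold, adjusted p = 0.0433) followed. The largest decreases were NPR3 (a natriuretic peptide receptor, 4.76-fold, adjusted p = 0.0483), NANOS1 (3.73-fold, adjusted p = 0.0327) and SLC17A4 (3.71-fold, adjusted p = 0.0363). DEFB119 (3.55-fold, adjusted p = 0.0229) and HSD3B2 (3.22-fold) followed. PLAAT4 (4.51), ERAP2 (4.53) and TLR1 (4.64) in mid-late and SLC17A4 (4.44) and DEFB119 (4.45) in late functional arrays did not exceed the 95th percentile of the NC set (4.64). The size of their folds and their order are therefore uncertain. None of these calls held in all 12 fits that left out 1 array: SAMD9L was called in 11, ST8SIA1 and DEFB119 in 8, ERAP2 in 7, SLC17A4 in 6, PLAAT4 in 5, NPR3 and NANOS1 in 4, TLR1 in 3 and HSD3B2 in 2.

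Antigen presentation genes were higher as a list (mean 0.93, 13 of 14 members above mid-late, camera adjusted p = 4.31e-06; adjusted p = 0.528 with an estimated correlation). None of them was called and 8 were adjusted over the list alone; CTSS (1.80, adjusted p = 0.074) and MAMU-DQA1 (1.65, adjusted p = 0.137) differed most. IRF1 rose by 1.35 (adjusted p = 0.0358) as the single called member of 18 interferon-stimulated genes, 4 of which rose adjusted over the list alone (camera adjusted p = 6.34e-05; adjusted p = 0.574 with an estimated correlation). SQSTM1 rose by 0.67 (adjusted p = 0.0495) among 17 lysosome and autophagy genes, 7 of which rose adjusted over the list alone (camera adjusted p = 0.000174; adjusted p = 0.465 with an estimated correlation). The macrophage list lay higher by a mean of 1.05 with 0 called members and 2 adjusted over the list alone (camera adjusted p = 0.000183; adjusted p = 0.574 with an estimated correlation); LYZ differed by 2.52 (adjusted p = 0.0611) and AIF1 by 1.48 (adjusted p = 0.149). AURKB fell by 0.56 (adjusted p = 0.0399) as the called member of 17 cell cycle genes, 10 of which fell adjusted over the list alone (camera adjusted p = 1.79e-05; adjusted p = 0.574 with an estimated correlation). The calls of the 5 lists held whichever single array was left out, but with the NC mean as a covariate only the cell cycle call remained. The macrophage list then turned to -0.13 and interferon-stimulated genes to -0.17. IRF1 and AURKB were called in 4 of the 12 fits and SQSTM1 in 3. The 28 lists without a called shift had camera adjusted p-values from 0.0852 to 0.881.

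limma called 470 probe sets between late functional and mid-late corpora lutea, 175 higher and 295 lower, 59 of them at least 2-fold. The share of higher calls was 37.2% as deposited, 56.2% after median centring and 25.2% after renewed quantile normalization. The count was 2417 without late regressed arrays 2 and 3, which share the estimate of the spread, 2682 with only these groups fitted, 3106 with array weights, 107 with the median filter on signal and 0 with the NC mean as a covariate. Leaving out single arrays gave 16, 19, 74 and 209 calls for mid-late arrays 1 to 4, 22, 4, 10 and 142 for late functional arrays 1 to 4, and 1008 for late regressed array 2.

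Across all 3 groups, limma's F test called 2587 probe sets, and 1742 without late regressed arrays 2 and 3. It called 297, 407, 623 and 1104 without mid-late arrays 1 to 4, 1336, 951 and 1039 without late functional arrays 1 to 3, and 5221 and 1049 without late regressed arrays 1 and 3. Differences of the late groups from mid-late correlated across probe sets, which are not independent replicates, with r = 0.639 and a covariance of 0.062. Unchanged groups simulated against shared mid-late arrays gave 0.501 and 0.017, so the covariance exceeded the simulated one by 0.045. The simulated noise was independent for each value, with 1 spread per probe set for all groups, unlike the real arrays. Its r of 0.501 therefore follows from the shared arrays alone, and the excess was not tested further. With 2 of the mid-late arrays as the baseline of each late group, so that no mid-late array was shared, r lay between 0.428 and 0.53. The covariance lay between 0.048 and 0.055 over 6 splits. The simulation, made with shared arrays, gives no reference for these values. Both comparisons called 113 probe sets higher and 272 lower, and 0 were called in opposite directions. They share the mid-late arrays, which by itself favours calls in the same direction, and no test was made of this overlap. For probe sets called with 2 of the mid-late arrays, late functional corpora lutea showed a mean of 0.61 of the late regressed change against the other 2, from 0.54 to 0.65 over the 4 of 6 splits with at least 20 calls. Both differences in this slope subtract the same 2 mid-late arrays, whose shared noise can raise it, and the selection reuses the late regressed arrays. The slope fell to 0.36 without late regressed arrays 2 and 3, to 0.33 without late regressed array 1 or array 4, and to 0.41 without late functional array 4.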

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

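Of the tests in this part, those of RNA degradation, luteal cell share, macrophage content and background were chosen only after the result was seen, and the regroupings of arrays before. Of 300 groups of 4 arrays examined for 1 array far from the rest, 27 stood out, where independent groups would give about 15 by chance. The groups cover measures such as control signals, list means and named genes on the same arrays. They are not independent, so this excess was not tested.

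Late regressed array 2 stood out in the 3′ minus 5′ difference of beta-actin (2.11, others 0.35 to 0.46) and GAPDH (2.94, others 0.55 to 0.94). Late functional array 4 stood out most often. Its oxidative phosphorylation mean was -0.41 (others -0.02 to 0.03) and its complement mean 0.70 (others 0.35 to 0.36). Its log2 values were 9.94 for SERPING1 (others 8.95 to 9.05), 4.17 for CCNB2 (5.72 to 6), 4.38 for CCNB1 (5.97 to 6.06), 5.47 for TYMS (7.31 to 7.66), 8.21 for PSMB8 (9.48 to 9.73), 7.77 for ISG15 (8.53 to 8.67), 8.68 for ST8SIA1 (7.81 to 7.95) and 6.92 for AIF1 (7.61 to 7.71). Late regressed array 3 stood out for GATA6 (8.34, others 8.85 to 8.89), IRF1 (8.20, others 7.11 to 7.16) and DEFB119 (3.52, others 3.85 to 3.91). Late regressed array 1 stood out for NANOS1 (7.59, others 6.25 to 6.40) and SLC17A4 (4.78, others 4.10 to 4.19), and array 4 for EGR2 (4.93, others 7.86 to 8.14). Mid-late array 1 stood out for IFI27 (11.86, others 12.95 to 13.11), ASAH1 (10.97, others 11.24 to 11.28), TAP1 (7.99, others 9.10 to 9.29) and PSMB8 (7.48, others 8.46 to 8.54). The remaining values were NR1H3 at 6.85 on mid-late array 3 (others 6.37 to 6.43), MGST1 at 11.02 on mid-late array 2 (10.20 to 10.33), SYNPO2 at 6.27 on mid-late array 4 (5.61 to 5.70), ATG5 at 8.27 on late functional array 2 (8.01 to 8.02) and SAMD9L at 9.03 on late functional array 3 (9.49 to 9.55).

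Late regressed arrays 2 and 3 stood apart from the other 10 arrays. Degraded RNA is a candidate explanation for array 2, whose 3′ minus 5′ difference of 2.52 exceeded the highest of those 10 arrays (0.70), but not for array 3, at 0.46. A lower share of luteal cells alone would raise markers of other cell types alike. On array 3 the macrophage list exceeded the endothelial list by 1.61 (SE 0.34 over members), so these lists did not rise alike there. That SE treats correlated genes of 1 array as independent, so the gap cannot decide whether a lower luteal share was the cause. More macrophages in that gland stay open too. On array 2 that gap was 0.31 (SE 0.55), which leaves a lower share of luteal cells open as well. A later point of regression in these animals was not tested.

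Interferon-stimulated genes lay higher on late functional than on late regressed arrays (difference -0.63, exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give). If macrophage content were the whole cause, the difference should vanish with the macrophage list as a covariate. It remained at -0.50 (exact permutation p = 0.0286) after removal of the macrophage list at its fitted slope of 0.53. The macrophage list itself differed by only -0.24 between these groups. The covariate could therefore remove little, and this test cannot decide the point. Of the 16 measured macrophage genes, 13 lay above the 95th percentile of the NC set on all mid-late arrays, and LYZ reached 11.15 in late functional arrays. Macrophage content stays open, the functional state itself stays open as an untested hypothesis, and so does an unrecorded batch.

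Many lower calls against mid-late lay at low signal. Of the NC set below its 95th percentile 7.66% were called lower in late regressed arrays, against 4.24% of other probe sets at such levels, so a background shift may account for lower calls at low signal. Above that level, lower calls were made with 2 arrays of each of these groups and measured on the arrays held out. Over the 15 of 36 splits with at least 20 such calls, their median decrease on held-out arrays had a median of 0.54 (0.16 to 0.80). Each of these splits had late regressed array 2 or 3 among the selecting arrays, and with both selecting the held-out medians ran from 0.155 to 0.238. The shift of the NC set, taken as constant on a linear scale, would give at most 0.015. That argues against such a constant shift as their whole cause, and other forms of background were not tested.

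Regroupings of the arrays were counted too. For late regressed against mid-late, 1 of 35 splits gave as many calls, the real one with 5282, and the highest other split gave 11. That share is the smallest that 35 splits can give, so chance is made unlikely but is not excluded. Regrouping cannot detect an unrecorded batch that follows the groups. The real grouping also gave the most calls for late functional against mid-late (1 of 35, 470 calls against a highest other of 0). It did so too for any difference among the groups (1 of 100 drawn splits, 2587 against 888). For late regressed against late functional, 5 of 35 splits gave at least the 1 real call, so the real grouping did not stand out from chance. The highest, with 923 calls, set late regressed array 1 with late functional arrays 1 to 3 against the rest, which points to a structure of the arrays that the progesterone groups do not follow.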

How the results depend on the processing

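The tests without late regressed arrays 2 and 3 together, with only probe sets above the NC percentile and with the NC covariate were chosen after the results were seen. All 26 list calls were lost with an estimated correlation, and their direction held. The same replicate numbers occur in each group without a stated pairing. Deviations of same-numbered arrays correlated between -0.12 and 0.3, above 0.1 in 3 of 12 pairs, and 4 of 12 arrays correlated best with their own number, so the arrays were not taken as paired. With the replicate number as a block, 4349 probe sets were called for late regressed against mid-late, 0 for late regressed against late functional, 4 for late functional against mid-late and 1545 in the F test, and all 26 list calls held. Of those 26, 7 were lost after centring, 8 with the median filter, 7 above the NC percentile, 4 with array weights, 4 with the 3′ to 5′ covariate, 2 with the mean over probe sets and 1 after quantile normalization. A further alternative, without arrays 2 and 3, lost 12. None of these turned a direction. In this order of the 4 tests, the main counts were 5282, 1, 470 and 2587. The cause of each move below was not tested unless stated.

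For late regressed against mid-late, the count was 1620 with only the groups compared, 2839 with array weights, 684 at 2-fold and 975 without late regressed arrays 2 and 3. Leaving out single arrays gave 2050 to 7532. For late regressed against late functional it was 10 with the median filter and also above the 95th percentile of the NC set, 2 after centring, 5 after quantile normalization, 15 with the trended robust prior, 11 with array weights, 0 with only the groups compared, with the 3′ to 5′ covariate, at 2-fold and without arrays 2 and 3, and 5 with the NC covariate. Leaving out single arrays gave 0 to 924. For late functional against mid-late it was 107 with the median filter, 72 above the NC percentile, 2682 with only the groups compared, 3106 with array weights, 883 with the 3′ to 5′ covariate, 59 at 2-fold and 2417 without arrays 2 and 3. Leaving out single arrays gave 4 to 1008. The F test gave 440 at 2-fold and 297 to 5221 without single arrays.

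With the NC covariate, 0 probe sets were called in either comparison with mid-late and 0 in the F test. The NC mean is lower on every late array than on every mid-late array, so the covariate follows the groups. HSD3B2 went from -3.11 (SE 0.33) to -2.54 (SE 0.59) for late regressed and from -1.69 (SE 0.33) to -1.20 (SE 0.53) for late functional arrays, so its calls ended with a smaller difference and a larger SE. With the NC covariate 14 list calls held and 8 were lost in the same direction, among them antigen presentation and lysosome genes for late functional arrays and LH receptor and progesterone synthesis for late regressed arrays, each against mid-late. Under that covariate the macrophage list turned to -0.59 for late regressed and -0.13 for late functional arrays against mid-late, interferon-stimulated genes to -0.17 for late functional arrays, and the complement list changed its tested direction at a mean of 0.042. Background and stage cannot be separated by this fit.

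STAR for late functional against mid-late, near 0, turned to 0.029 after centring, 0.019 after quantile normalization, 0.058 with array weights and 1.08 with the NC covariate, and ranged from -0.081 to 0.098 without single arrays. NR1H3 for late regressed against late functional turned to -0.57 without arrays 2 and 3 and ranged from -0.011 to 0.722 without single arrays. The 3′ to 5′ difference ranged from -0.11 to 0.58 for late regressed against mid-late, from -0.03 to 0.66 against late functional, and from -0.09 to -0.06 for late functional against mid-late, with an exact permutation p of 0.0286 whichever mid-late array was left out and 0.0571 whichever late functional array was left out. The correlation of the late differences was 0.691 without arrays 2 and 3 and 0.544 to 0.696 without single arrays. The share of the regressed change seen in late functional glands was 0.53 with the median filter, 0.36 without arrays 2 and 3 and 0.33 to 0.65 without single arrays, over the 5 of 12 such fits that could give it (late functional arrays 1 and 4, late regressed arrays 1, 2 and 4). Of 69 called named results, 31 kept their call without arrays 2 and 3, 49 with the block and 58 with the 3′ to 5′ covariate, and their direction held in each. Without single arrays, 24 of the 56 named calls for late regressed against mid-late and 0 of the 13 for late functional against mid-late held throughout, as did 4 of 11, 5 of 10 and 5 of 5 list calls in the order of the comparisons above. Signal near background limits the calls at low values.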

Other observations

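The tests in this part were chosen after the data were seen. Late functional corpora lutea were also set against the mean of both other groups with limma, which called 9 probe sets higher and 1 lower, with 4788 at an unadjusted p below 0.05. CACNB2, a calcium channel subunit gene, was 6.58 ± 0.20 in late functional, 4.80 ± 0.16 in mid-late and 5.18 ± 0.38 in late regressed arrays (n = 4 each, limma adjusted p = 0.00497), and a second probe set of the gene was also called (adjusted p = 0.0277). ERAP2 was called with both of its listed probe sets, at 6.11 ± 0.10, 4.53 ± 0.40 and 4.44 ± 0.40 on the brighter of them (adjusted p = 0.0156). KALRN (6.06 ± 0.63 against 4.28 ± 0.09 and 4.01 ± 0.48, adjusted p = 0.0417), SAMD9L (adjusted p = 0.0139), ST8SIA1 (adjusted p = 0.0416) and RTP4 (adjusted p = 0.0429) were higher as well, and FAM210B was lower (adjusted p = 0.00497). KALRN, ERAP2 and RTP4 in the other groups lay below the 95th percentile of the NC set (4.64), so the size of their differences is uncertain. RTP4 was 4.91 ± 0.17 in late functional, 4.05 ± 0.17 in mid-late and 4.31 ± 0.16 in late regressed arrays.

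Late functional arrays 1, 2 and 3 resembled each other more than any other arrays of a group. The SD of their log2 differences ran from 0.196 to 0.203, with 0.03% to 0.11% of probe sets more than 2-fold apart, and mid-late arrays 3 and 4 followed at 0.208 and 0.2%. No more than 0.095% of values were identical within a pair of late functional arrays, so these are not copies of one file. Late functional array 4 differed from the other late functional arrays by SDs of 0.34 to 0.346, and pairs of late regressed arrays by 0.368 to 0.564. DEFB122 was 8.01, 7.94, 7.44 and 4.68 on late functional arrays 1 to 4 and between 4.99 and 5.84 on late regressed arrays.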
